A study of Mus musculus with 4 samples.

How the data were processed

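Cells from B16F10 tumors were labelled with hashtag antibodies, pooled within a treatment and then sorted for CD45, per the labels' protocols. At least 50000 cells per group were sorted, and sorted cells were run on a droplet platform that captures the 3' ends of transcripts. Each tumor was started from 100000 cells in mice that were 8 weeks old, of both sexes. The labels give 4 libraries, 1 for each treatment. The submitters' processing notes name Bowtie 1.1.1 and the builds GRCm38 and mm10, without a role for either. The counting tool, the filters on cells and the treatment of doublets are not given in the sources used here.

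The values used are text from a single description sheet made by the submitters, with 1 line per hashtagged replicate. For each replicate it gives the hashtag, the barcode sequence, the treatment and, where the replicate was kept, the names of 4 processed files. Those processed files were not used here. The sheet holds no counts, normalized values or depths, so neither the sequencing depth nor the precision of any expression value can be stated. 8 columns of the sheet were read. A line was assigned to a treatment group where its treatment text equalled the treatment label of a sample, which held for 16 of 16 replicates. A replicate was called kept when all 4 file names were filled in. This was checked against the sheet's closing remark on dropped replicates, and both gave the same call for 16 of 16 replicates. Whether each replicate came from a separate animal is not stated in these sources.

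Shares of replicates kept were given exact Clopper-Pearson 95% intervals, with Wilson intervals as an alternative. The placement of drops over hashtags was tested by enumerating every placement of 1 drop in each group, and the statistic was the highest number of drops on a single hashtag. This test and its variant with drops on any replicate were chosen after the layout had been seen. Barcodes were compared by Hamming distance, with edit distance as an alternative. Leaving out each hashtag in turn was a further alternative. All were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and the plot was drawn with matplotlib 3.10.9.

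Tests of expression, cell type shares and cell numbers between treatments had been planned on condition that the sheet held such values, together with a rule for named genes and lists of cell type markers. It did not, so none of them was run and no gene was named. The mouse annotation was not used.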

Results

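Immune cells were profiled by droplet-based single-cell RNA sequencing from subcutaneous B16F10 tumors of C57BL/6J mice under 4 treatments. B16F10 is a mouse melanoma line of C57BL/6 origin, so its tumors grow in hosts with an intact immune system. The cells were sorted for CD45, the surface phosphatase that marks cells of the hematopoietic lineage. The groups were vehicle (PBS), BVT948, cisplatin, and BVT948 given with cisplatin. BVT948 is an inhibitor of protein tyrosine phosphatases, and cisplatin is a platinum drug that crosslinks DNA. Dosing began on day 8 after implantation, when tumors could be felt, with 10 mg/kg for BVT948 and 5 mg/kg for cisplatin. PBS, BVT948 alone and cisplatin alone were injected into the peritoneum, with PBS and BVT948 given daily. Cisplatin was given on 3 days in each of 2 rounds that lay 3 days apart, and the combination followed a schedule like that of each drug alone, per the sample labels. The series text instead speaks of 2 doses of cisplatin, so the number of injections is uncertain. The values analysed here are the submitters' record of how replicates, hashtags and treatments were arranged. Gene expression, cell types and cell numbers were not analysed here, so no gene is reported as higher or lower in any group. Sequencing depth per replicate is unknown from this record.

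The first comparison asked how many replicates each treatment retained after quality control. The record listed 16 hashtagged replicates, 4 in each of the 4 treatment groups, and 12 were kept. The number kept was equal in the 4 treatments. Vehicle, BVT948, cisplatin and the combination each kept 3 of 4 replicates and lost 1, or 75.0% with an exact Clopper-Pearson 95% interval of 19.4% to 99.4%. Over the whole series the share kept was 75.0% (12 of 16, exact 95% interval 47.6% to 92.7%). These intervals cover counting error only, and with 4 replicates per group they leave room for large differences in retention. The dropped replicates were B3 (BVT948), Cisplatin3 (cisplatin), Combo2 (combination) and Vehicle3 (vehicle). The submitters gave few cells or poor reads as the grounds, without saying which applied to which replicate and without a threshold.

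Retention was then compared between hashtags. The hashtags are antibodies against mouse surface proteins that carry a synthetic DNA barcode, so that cells of pooled replicates can be assigned to their replicate after sequencing. Hashtags 1 and 4 were kept in all 4 groups. Hashtag 2 was kept in 3 of 4 groups and was lost in the combination. Hashtag 3 was kept in 1 of 4 groups, the combination, which is 25.0% with an exact Clopper-Pearson 95% interval of 0.631% to 80.6%. Of the 4 dropped replicates, 3 therefore carried hashtag 3 and 1 carried hashtag 2. With 1 drop placed at random in each group, 52 of the 256 possible placements put at least 3 drops on a single hashtag (exact permutation p = 0.203, one-sided). The concentration of drops on hashtag 3 did not pass the 0.05 threshold. Only all 4 drops on a single hashtag could have passed, so this result is no evidence against an effect of the hashtag.

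**Figure D1:**
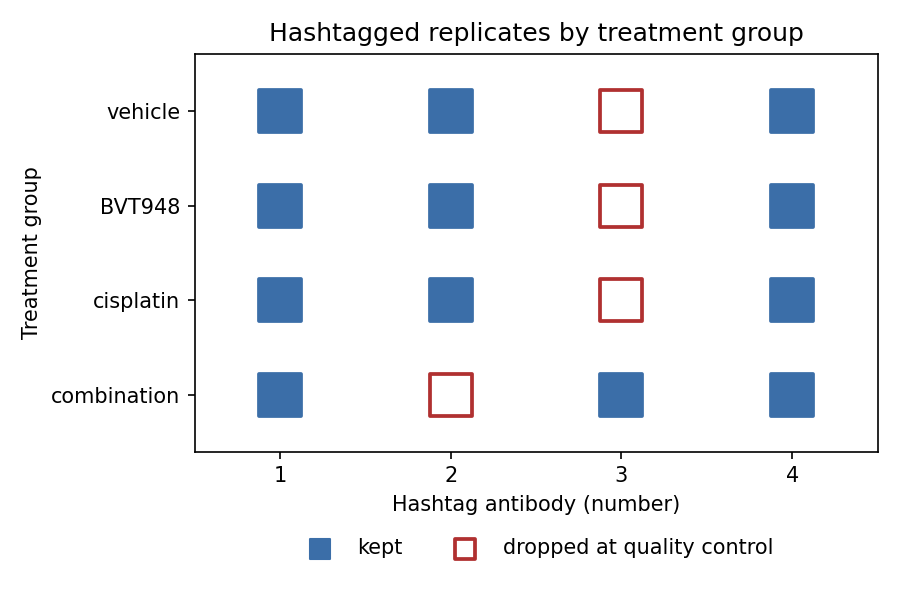
Each square is 1 hashtagged replicate, placed by hashtag number (horizontal axis) and treatment group (vertical axis); filled squares were kept and open squares were dropped at quality control. Each group kept 3 of 4 replicates, and 3 of the 4 open squares lie in the column of hashtag 3.

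The design implies 5 comparisons of treatment, namely each treated group against vehicle and the combination against each single drug. All 5 set 3 kept replicates against 3. For a single value such as the share of a cell type, a two-sided exact permutation test of 3 against 3 has 20 arrangements and cannot give a p below 0.1. Such a test takes the replicates as independent, and whether each came from a separate animal is not stated in these sources. With the 4 replicates per group that were prepared, the smallest p was 0.0286, from 70 arrangements. Both limits hold for 1 comparison and are not adjusted for the 5 comparisons. BVT948 and cisplatin shared all 3 kept hashtag numbers with vehicle. The combination shared 2 kept hashtag numbers with vehicle, 2 with BVT948 and 2 with cisplatin, because it alone kept hashtag 3 and lacked hashtag 2. The same hashtags were used in every group, so a hashtag identifies a replicate only within its treatment. The labels list 1 library for each treatment, so differences between libraries and between treatments cannot be told apart from the labels.

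The barcodes themselves were compared because the assignment of cells to replicates rests on them. They are synthetic, and no match to the mouse genome was sought. Hashtag 1 carried ACCCACCAGTAAGAC, hashtag 2 GGTCGAGAGCATTCA, hashtag 3 CTTGCCGCATGTCAT and hashtag 4 AAAGCATTCTTCACG, each 15 nt long. Across the 6 pairs the Hamming distance, the number of positions with different bases, ranged from 11 to 13. Hashtags 1 and 2 formed the closest pair by this measure, at 11 differing positions, and the nearest barcode to hashtag 3 differed at 12 positions. By edit distance, which allows insertions and deletions, hashtags 2 and 3 were instead the closest pair at 8, and hashtags 1 and 2 were among the farthest at 11. The GC content was 53.3% for hashtags 1, 2 and 3 and 40.0% for hashtag 4.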

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

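The alternatives were fixed before the data were examined, except both placement tests of drops. Counting each distinct barcode once gave 100% kept in place of 75.0%, because each of the 4 barcodes was kept in at least 1 group. Leaving out lines with no group or hashtag removed none of the 16 replicates. Leaving out each hashtag in turn gave between 66.7% and 91.7% kept, the highest without hashtag 3, and all of these lay inside the exact interval of 47.6% to 92.7%. These shares use the same replicates as the interval, so lying inside it is no independent support for stability. The Wilson interval for 1 group began at 30.1% in place of 19.4%. With edit distance the smallest distance between barcodes was 8 in place of 11, and the closest pair was hashtags 2 and 3. For barcodes of equal length edit distance cannot exceed Hamming distance, so only a fall or no change was possible. Placing the 4 drops on any of the 16 replicates gave an exact p of 0.108 in place of 0.203 for at least 3 drops on a single hashtag, still above the 0.05 threshold. There too, only all 4 drops on a single hashtag could have passed. The alternatives planned for cell numbers and for expression (normalization, a filter on low counts, leaving out replicates and a replicate block) were not run, since the sheet holds no such values. No paired analysis was possible because the sheet gives no measured value per replicate.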

Other observations

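The placement tests and the question put to the barcode of hashtag 3 were chosen after the layout had been seen, while the barcode distances themselves had been planned. Of the 4 dropped replicates, 3 carried hashtag 3 and 1 carried hashtag 2. Chance placement of 1 drop in each group stays open as an explanation, with an exact p of 0.203. Misreading the hashtag 3 barcode as another would need at least 8 edits, or 12 substitutions, in 15 nt. Distances this large argue against misread bases turning this barcode into another. Other forms of mix-up between hashtags stay open, because no hashtag reads were analysed here. The order of the distances points both ways and does not decide whether hashtag 3 has the barcode most easily misread. By Hamming distance the nearest barcode to hashtag 3 lies at 12, and hashtags 1 and 2 lie closer to each other at 11. By edit distance hashtags 2 and 3, which carried all 4 drops, are the closest pair at 8. A weakness of hashtag 3 staining was not tested, nor was a biological explanation, since the design names none that follows the hashtag number. The replicate number in each name equals the hashtag number. An effect of the hashtag therefore cannot be told apart from anything else that follows the replicate number.

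The kept replicates carried hashtags 1, 2 and 4 in vehicle, BVT948 and cisplatin, and hashtags 1, 3 and 4 in the combination. Any readout that depends on the hashtag number is therefore partly confounded with the combination treatment, for which 2 hashtag numbers are shared with the other groups.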
